A study of Sinorhizobium meliloti and Sinorhizobium meliloti
Medicago truncatula with 18 samples.

How the data were processed

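The series holds 18 strand-specific RNA sequencing libraries of Sinorhizobium meliloti strain 2011 in 6 groups of 3: long and short RNA of exponential culture, of stationary culture and of 10-day-old nodules. Per the labels' protocols, nucleic acids of cultures were released with a detergent and protease lysis and nodules were ground in liquid nitrogen. Total RNA was isolated with the mirVana kit and treated with DNase. Ribosomal RNA of bacterium and host and 1 abundant bacterial tRNA were depleted with capture oligonucleotides, and RNA was parted at 200 nt. Adaptors were ligated to RNA so that strand was kept. Per the labels, long RNA was fragmented and short RNA was not but was treated with tobacco acid pyrophosphatase, which turns 5′ triphosphate ends into ligatable ones. Inserts of 150 to 250 nt were selected for long RNA of nodules, 50 to 120 nt for long RNA of cultures and 20 to 120 nt for all short RNA. Effects of depletion, insert range and plant RNA on the nodule libraries were not measured, and within long RNA the insert range goes with the state. The protocol text in the labels breaks off, so later steps of library preparation were not used here.

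The deposited files give, for each replicon, strand and base, the sequencing coverage of each library: the deposited signal is a depth in whole numbers, not counts per gene and not normalised, per the file headers and the values. The build, per the file headers, is an assembly of strain 2011 with 3 replicons. The aligner, its settings and the treatment of reads with several matches are not given in the sources used here. A test of the files found no depth of 1 or 2, a lowest listed depth of 3 and a highest of 1000, so weakly covered bases are listed at 0 and deep ones are cut at a ceiling. Where a window holds a base at 1000 its level is understated. All 18 columns of depth were used, and each was tied to its library by its name.

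The plan fixed before the data were examined took annotated genes as features, ribosomal RNA genes left out, with size factors from protein-coding genes. The gene table at hand belongs to another strain and assembly and was not used here, so the planned fallback applied: windows of 500 nt per strand, 26776 in all. The 14 gene lists fixed in advance, the rules that name genes by list or symbol, and the antisense share of genes are void for the same reason. Depth on ribosomal RNA and other structural RNA genes could not be left out, and the antisense share was replaced by the share of depth on the less covered strand of each pair of facing windows, a measure chosen after the files were seen. Replicon shares were taken over all depth instead of protein-coding genes.

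The mean depth of each window was divided by a median-of-ratios size factor, taken over the windows above 0 in all 9 libraries of a fraction (1644 in long, 5148 in short RNA), and analysed as log2(depth + 0.5). Size factors in long RNA were 1.92 to 2.96 in exponential culture, 1.23 to 2.09 in stationary culture and 0.167 to 0.375 in nodules, so the lowest listed depth of 3 is a normalised depth of 1.01 to 2.44 in cultures and 8.01 to 18.0 in nodules. Windows with a mean normalised depth of 1 or more over the 9 libraries were tested, 9114 in long and 12340 in short RNA. The 9 libraries of a fraction entered 1 limma fit with a mean-variance trend and no covariate. Each of the 3 pairs of states was a contrast, and a window was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(depth + 0.5) scale. Where the lower state lies under the floor of the files they rest on depths listed at 0 and can overstate the change, so the smallest fold that the floor allows was computed for each named window, with every unlisted base of the lower state at a depth of 3. This bound uses the size factors above and was not computed with others, so it allows for the floor but not for the scaling. With 3 libraries against 3, shares were compared by exact two-sided permutation tests, whose smallest p is 0.1. All 18 pairs of replicates differed by more than sampling noise (chi-square per degree of freedom 2.99 to 25.1 over window sums in reads of 50 nt), so none was treated as a copy of another.

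The named windows follow a rule fixed in advance for genes and applied to windows: per comparison the 6 largest rises and 6 largest falls in long RNA, and 4 and 4 in short RNA, among windows called, without overlap between the libraries of both states and with a mean of at least 10 in the higher state. Runs of at least 4 adjacent windows called in the same direction as deposited and at matched depth were defined after the data were seen. Those named come from the 4 longest and the 4 with the largest mean change per comparison and direction, plus a few others singled out after their values were seen. Not every run picked by that rule is printed, so those shown are not the whole set. The level of a run is the mean over its windows, and a single window can carry much of it.

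The fit was tested on simulated depths drawn for the windows tested, with 50-nt reads, the floor of 3, the ceiling of 1000, the libraries' size factors, a log2 SD of 0.25 between replicates and 200 windows changed by 2 or 4 times in each of the 2 states set against exponential culture. All percentages of this test are of simulated windows that passed the depth filter, so changed windows lost to the filter are not counted as missed. For stationary against exponential culture in long RNA, 7074 of the 9114 windows simulated passed. Of these, 47.5% of windows changed 4 times and 11.7% of those changed 2 times were recovered, and no unchanged window was called. For nodules against exponential culture, 41.4% of unchanged windows were called lower, because the floor lies higher in shallow libraries. For this reason a matched depth was added: reads of 50 nt laid along the depth of each deeper library were kept at random in proportion to the size factors, then the same floor and ceiling were applied. Long RNA of exponential culture dropped from a relative depth of 2.52 to 1.82 at 50 nt after the 5′ rises of short RNA, which is the ground for the length of 50 nt; long RNA of nodules had no such drop (1.87 and 1.87), so the reads of nodules could be longer than those simulated. In the simulation of nodules against exponential culture in long RNA, 4375 windows passed the filter at matched depth. There, 0.0937% of unchanged windows were called lower and none higher. Of those changed 4 times 62.0% were recovered, and of those changed 2 times 25.5%. The simulation gave all libraries the same SD and took the levels of all states from exponential culture. Real long-RNA replicates of nodules correlated at r = 0.782 to 0.816 across windows, and those of a culture state at 0.977 to 0.992. The rates thus hold for the simulated spread, and false calls can be more frequent in the real nodule comparisons. A first form without resampling called 13.3% of unchanged windows higher and was replaced because of this, and its values are given with the alternatives.

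The alternatives fixed in advance were size factors from total depth and from the upper quartile, quantile normalisation, pseudocounts of 0.1 and 2, no depth filter and a filter of 10, the median depth of a window, a 2-fold minimum, a replicate block, a fit of the 6 libraries compared, voom precision weights, and leaving out each library in turn. For shares they were the median depth times length, leaving out the 10 windows with the most depth and leaving out each library. Those added after the data were seen were matched depth, matched depth with total depth or recomputed size factors, the form without resampling, and leaving out windows at the ceiling. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.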

Results

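RNA of Sinorhizobium meliloti strain 2011, a soil bacterium that fixes nitrogen inside the root nodules of Medicago, was sequenced in 3 states: exponentially growing culture, stationary culture, and 10-day-old nodules of the legume Medicago truncatula, whose bacteria the labels describe as differentiated into nitrogen-fixing bacteroids. From each state, RNA longer than 200 nt (long RNA) and RNA shorter than 200 nt (short RNA) were sequenced separately, with 3 replicate libraries each, 18 libraries in all. The title of the series names the annotation of this genome as its purpose, and the libraries show which strand of which region was transcribed in each state. The genome has 3 replicons, called a (1352561 nt), b (1683348 nt) and c (3657276 nt) in the files. By letter and length these are the megaplasmids pSymA and pSymB and the chromosome. pSymA is known to carry genes for nodulation and nitrogen fixation, pSymB genes for exopolysaccharide synthesis and nutrient uptake, and the chromosome most housekeeping genes. The positions below are those of the files' own assembly, and no gene annotation of that assembly was used here, so regions are named by replicon, strand, start and end.

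The nodule libraries were far shallower than those of cultures. The depth summed over all bases of both strands was 114 to 176 Mb in the long-RNA libraries of exponential culture, 70.4 to 114 Mb in those of stationary culture and 4.11 to 8.52 Mb in those of nodules. In short RNA the sums were 134 to 206 Mb, 62.2 to 117 Mb and 11.8 to 19.02 Mb. Between 28.9% and 33.9% of the strand positions had listed depth in long RNA of exponential culture. In nodules it was 3.52% to 6.84%. The files list no depth of 1 or 2, only 0 and 3 or more, so a region listed at 0 in nodules was not detectable at their depth. Levels below are mean normalised depths per base with the SD over 3 libraries, and tests are limma's with Benjamini-Hochberg adjustment over the windows of 500 nt tested. The labels do not say whether replicates were separate cultures or plants, so p-values speak for these libraries only. Each p-value rests on a spread shared by the 9 libraries of a fraction, not on that of the states compared alone. Across windows, nodule replicates correlated at r = 0.782 to 0.816 in long and 0.838 to 0.866 in short RNA. Replicates of a culture state did so at 0.977 to 0.992 and 0.962 to 0.983. The shared spread can thus be too small for nodules. The level of a window with a base at the ceiling of 1000 is understated.

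In long RNA, stationary culture was compared with exponential culture. The reverse strand of replicon b from 22001 to 29500 rose from 1.19 ± 0.0594 in exponential to 158 ± 9.001 in stationary culture (SD, n = 3 each). On the chromosome, the forward strand from 3269501 to 3279000 rose from 3.56 ± 0.168 to 117 ± 5.55 and that from 3164001 to 3170000 from 1.71 ± 0.0699 to 144 ± 16.8. The reverse strand from 779001 to 781500 rose from 0.434 ± 0.0589 to 134 ± 42.4. On replicon a, the reverse strand from 798501 to 801000 rose from 0.797 ± 0.0934 to 69.3 ± 5.36. The falls were longest on the forward strand of the chromosome, where adjoining runs from 1460501 to 1477500 and from 1478001 to 1493500 fell from 178 ± 2.42 to 5.03 ± 0.198 and from 220.0 ± 0.672 to 5.67 ± 0.326. In 24 of the 34 windows of the first and 27 of the 31 of the second, a library had a base at the ceiling. The levels of these runs are thus understated.

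The forward strand of the chromosome from 1377501 to 1397000, at 19.5 kb the longest run that fell, went from 36.1 ± 1.83 to 2.90 ± 0.477, and without its first window from 32.6 ± 2.27 to 0.898 ± 0.0887. The reverse strand from 1235501 to 1239000 fell from 79.6 ± 3.22 to 0.743 ± 0.123. By the rule for single windows, 5 of the 6 largest rises lay next to each other on the reverse strand of replicon b between 27001 and 29500. The window from 28501 to 29000 there rose by 8.46 ± 0.13 (log2 change ± SE, adjusted p = 1.8e-08), from 0.910 ± 0.0662 to 499 ± 56.7, at least 331 times with the unlisted bases of exponential culture at the floor. The largest fall was on the reverse strand of the chromosome from 1238001 to 1238500, which fell by 7.13 ± 0.12 (adjusted p = 1.8e-08), from 135.5 ± 12.8 to 0.470 ± 0.0508, at least 69.5 times by the same bound. Of 9114 windows tested, 2922 were higher and 3677 lower in stationary culture. Windows of replicon a were more often higher (454) than lower (214), and so were those of replicon b (823 against 420), while windows of the chromosome were more often lower (3043) than higher (1645). Runs of at least 4 adjacent windows called in the same direction numbered 170 higher and 303 lower, and 266 of the lower ones lay on the chromosome. The median log2 change of all windows was -0.17, and -0.06 with libraries scaled to their total depth.

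**Figure D1:**
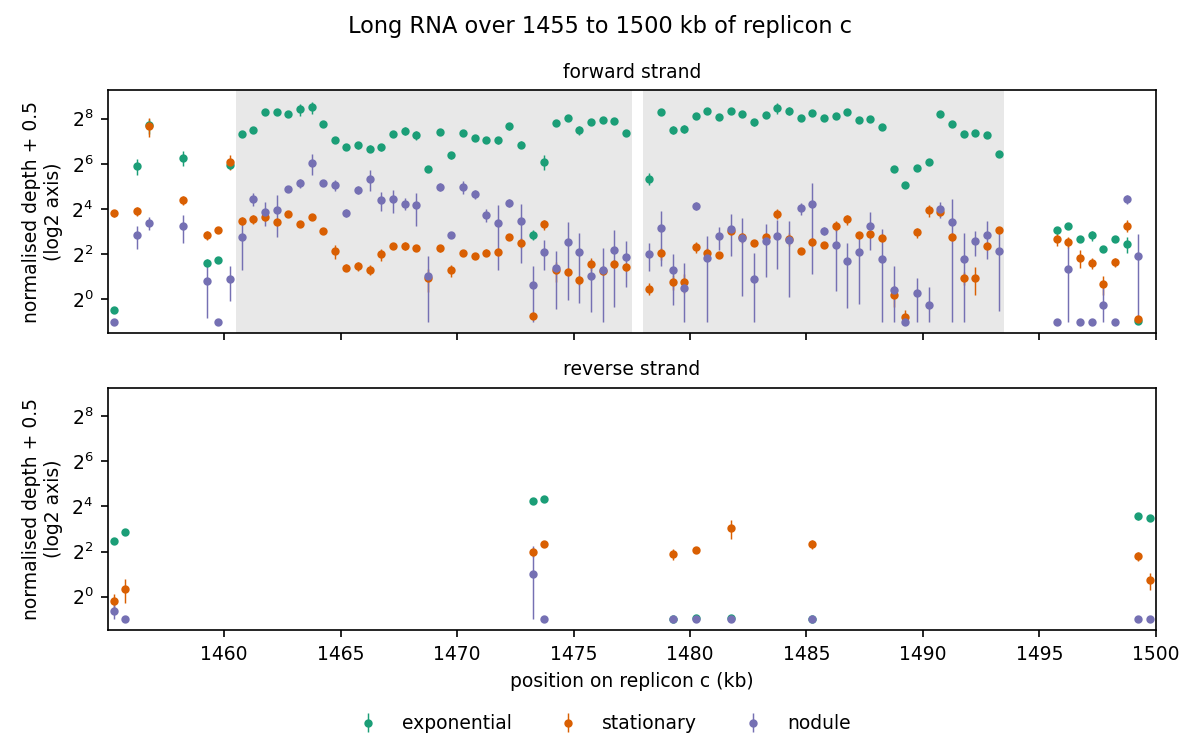
Normalised depth plus 0.5 of long RNA (log2 axis) in 500-nt windows over a stretch of the chromosome around 2 adjoining runs that fell, forward strand above and reverse strand below; points are means and bars SDs of 3 libraries, cut at 0.5 at the lower end, and windows below the depth filter are not drawn. In the shaded runs from 1460501 to 1477500 and from 1478001 to 1493500 the exponential means of 178 and 220.0 stand above the stationary means of 5.03 and 5.67. Most windows of these runs hold a base at the ceiling of 1000 in a library, so their levels are understated.

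In long RNA, nodules were next compared with exponential culture. The regions that rose most in nodules lay on replicon a. The forward strand from 453001 to 463000 was at 131 ± 33.3 in nodules against 0.485 ± 0.00666 in exponential culture (SD, n = 3 each). The reverse strand from 442001 to 451500 was at 131 ± 19.2 against 0.454 ± 0.0106. The forward strand from 412501 to 422500 was at 70.0 ± 7.07 against 0.514 ± 0.0490, and the reverse strand from 662001 to 672000 at 46.4 ± 4.34 against 0.0374 ± 0.00980. These 4 runs, the longest of those higher in nodules, cover 39.5 kb and held 72.2% ± 3.62 of the nodule depth on replicon a, against 0.634% ± 0.0136 of the exponential depth. Over the same bases short RNA was at 101, 151, 65.0 and 28.3 in nodules, and at 1.02, 1.45, 1.64 and 0.633 in exponential culture.

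Outside replicon a, the reverse strand of the chromosome from 1619501 to 1623500 rose from 18.0 ± 2.14 to 170.1 ± 4.43, and that from 3361501 to 3367000 from 2.02 ± 0.0956 to 50.0 ± 3.61. On replicon b, the forward strand from 609001 to 611000 rose from 1.09 ± 0.117 to 33.5 ± 4.74. The stretch of the chromosome that fell in stationary culture was low in long RNA of nodules too: the forward strand from 1460001 to 1477500 was at 16.8 ± 0.212 against 175 ± 2.13, and that from 1478001 to 1493500 at 6.03 ± 2.54 against 220.0 ± 0.672. Short RNA over the same bases was at 45.8 ± 7.97 in nodules against 67.9 ± 12.3 in exponential culture in the run from 1460001, and without its first window at 28.9 ± 2.99 against 67.3 ± 12.5. It was at 10.98 ± 0.441 against 87.8 ± 11.8 in the run from 1478001. In long RNA, 25 of the 35 windows of the run from 1460001 and 27 of the 31 of the run from 1478001 had a base at the ceiling in a library. The forward strand from 1606501 to 1621000 fell from 57.8 ± 2.36 to 2.26 ± 0.783, and that from 731001 to 736000 from 65.9 ± 5.09 to 0.371 ± 0.212. Among single windows, the reverse strand of replicon a from 671001 to 671500 rose by 8.74 ± 0.18 (adjusted p = 6.5e-09), from 0.293 ± 0.119 to 338 ± 47.3, at least 261 times with unlisted bases at the floor. All 6 windows with the largest rises lay on replicon a and all 6 with the largest falls on the chromosome. The chromosomal windows from 1930501 (reverse strand, 250.2 ± 3.76 in exponential culture) and from 398001 (forward strand, 232 ± 5.81) were listed at 0 in the 3 nodule libraries, falls of at least 19.4 and 17.98 times with every nodule base taken at the floor of 3. These bounds depend on the size factors and were not computed with other scalings.

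As deposited, 885 of 9114 windows were higher and 6726 lower in nodules, so that 88.4% of the calls were lower. With every library resampled to the normalised depth of the shallowest, a setting added after the data were seen, 776 of 6006 windows were higher and 3214 lower, 80.6% of the calls. With size factors from total depth at matched depth the lower share was 71.7%. Windows called both ways in the same direction numbered 692 higher and 3192 lower, and the runs above consist of windows among these. The direction of the balance on replicon a turned with depth: 220 windows were higher and 566 lower as deposited, but 182 higher and 134 lower at matched depth. On the chromosome lower calls outnumbered higher ones at matched depth as well (2785 against 460). The median log2 change of all windows was -2.58 as deposited, -1.37 after quantile normalisation, -2.10 at matched depth and -1.24 at matched depth with total depth size factors. With a pseudocount of 0.1 it was -4.29. Unchanged windows of the simulation had a median of -1.08 as deposited and -0.13 at matched depth. The size of the fall thus depends on the floor, the scaling and the pseudocount. The long-RNA nodule libraries also held longer inserts (150 to 250 nt) than those of cultures (50 to 120 nt), a difference that no comparison here can separate from the state.

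**Figure D2:**
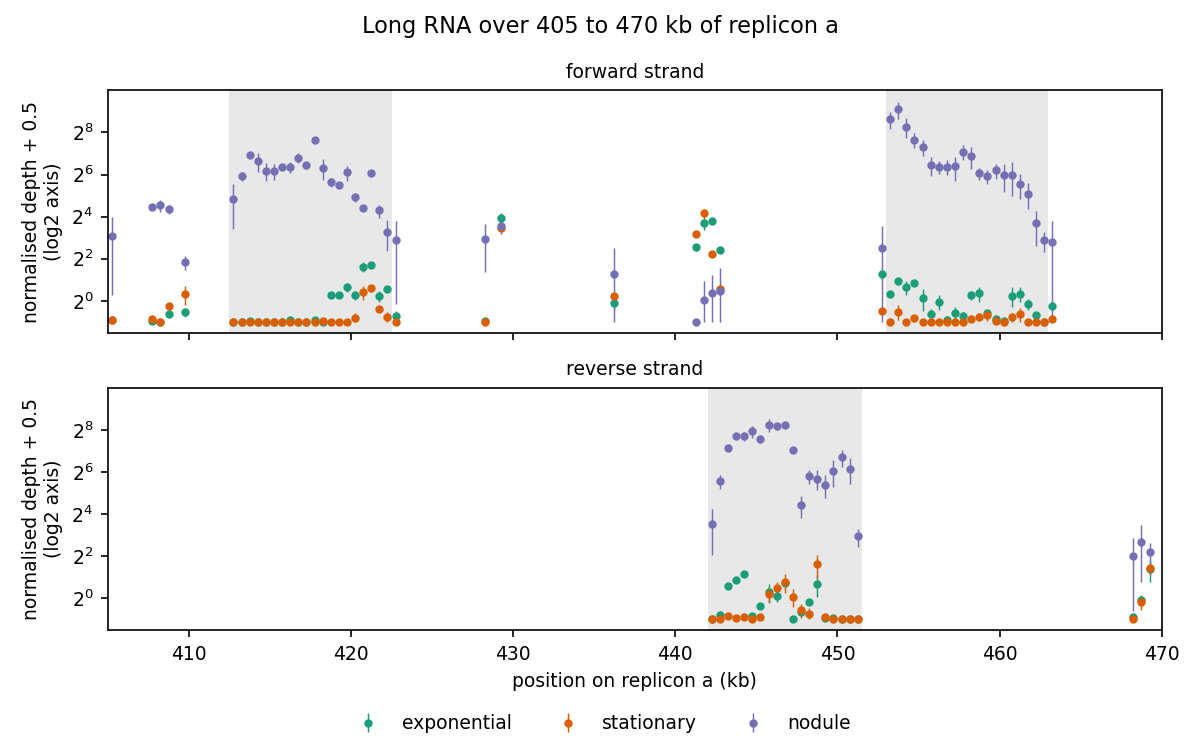
Normalised depth plus 0.5 of long RNA (log2 axis) in 500-nt windows over the stretch of replicon a that holds 3 of the 4 longest nodule runs, forward strand above and reverse strand below; points are means and bars SDs of 3 libraries, cut at 0.5 at the lower end, and windows below the depth filter are not drawn. In the shaded runs from 412501, 442001 and 453001 the nodule means are 70.0, 131 and 131, and those of exponential culture 0.514, 0.454 and 0.485.

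Nodules were also compared with stationary culture in long RNA. The same regions of replicon a were high in nodules: the forward strand from 453001 to 463000 was at 0.0382 ± 0.00737 in stationary culture against 131 ± 33.3 in nodules, and the reverse strand from 442001 to 451500 at 0.334 ± 0.0594 against 131 ± 19.2 (SD, n = 3 each). On the chromosome, the forward strand from 1556001 to 1562500 rose from 5.28 ± 0.482 in stationary culture to 111 ± 5.16 in nodules, and the reverse strand from 1874501 to 1881000 from 5.16 ± 0.833 to 59.1 ± 6.53. Several regions that were high in stationary culture had hardly any listed depth in nodules, where a base below a normalised depth of 8.01 to 18.0 is listed at 0. The forward strand of the chromosome from 3269501 to 3279000 fell from 117 ± 5.55 to 0.0858 ± 0.108, its reverse strand from 3171001 to 3174000 from 167 ± 2.08 to 0.0641 ± 0.111, and its forward strand from 52001 to 55500 from 149.8 ± 9.58 to 0.0343 ± 0.0594. The reverse strand of replicon b from 24501 to 29500 fell from 235 ± 13.1 to 0.862 ± 0.597.

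Inside the stretch that was highest in exponential culture, the forward strand of the chromosome from 1462501 to 1468500 was at 29.7 ± 2.24 in nodules against 5.83 ± 0.409 in stationary culture. The window with the largest rise, from 453501 to 454000 on the forward strand of replicon a, rose by 9.62 ± 0.28 (log2 change ± SE, adjusted p = 1.5e-08), from 0.2003 ± 0.174 to 554 ± 154. With the unlisted bases of the lower state at the floor, this is at least 293 times. The windows of replicon b from 28501 (499 ± 56.7 in stationary culture) and of the chromosome from 3278001 (438 ± 64.5) were listed at 0 in the nodule libraries, falls of at least 38.8 and 34.0 times with every base taken at the floor, under the size factors used here. As deposited, 903 windows were higher and 6305 lower, 87.5% of the calls lower. At matched depth 774 were higher and 2860 lower, 78.7% lower, and with size factors from total depth at matched depth 70.1%. In the same direction both ways were 708 higher and 2835 lower windows, of which 320 lay in 39 runs higher and 1067 in 180 runs lower. The median log2 change was -2.21 as deposited, -1.20 after quantile normalisation, -1.54 at matched depth and -0.80 at matched depth with total depth size factors. With a pseudocount of 0.1 it was -3.76. Unchanged windows of the simulation had a median of -1.05 as deposited and -0.11 at matched depth in this comparison.

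**Figure D3:**
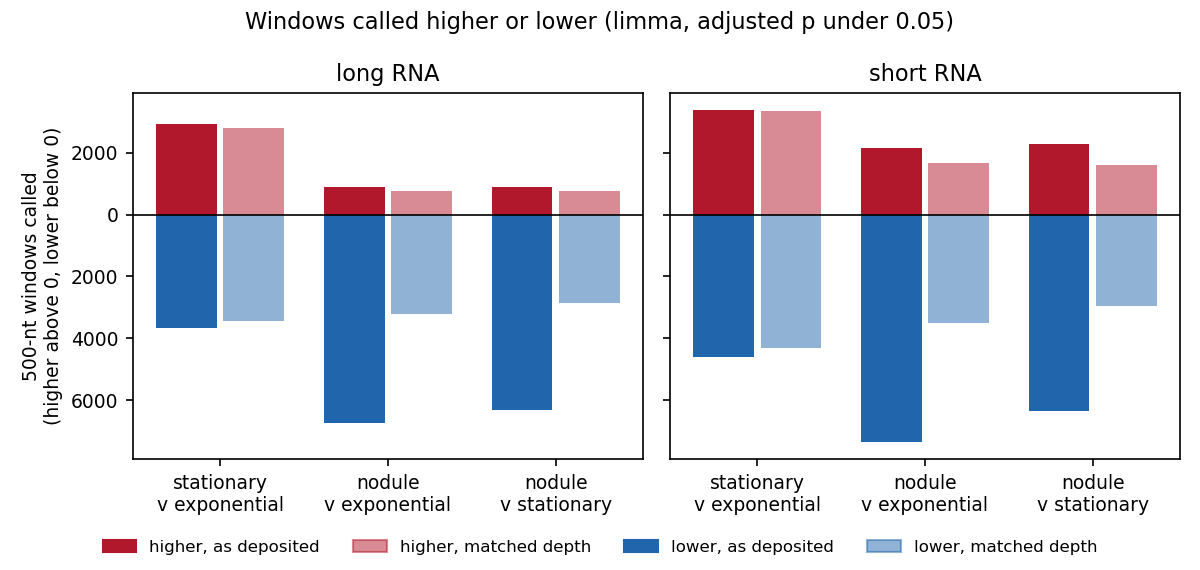
Number of 500-nt windows called higher (above 0) or lower (below 0) by limma at an adjusted p under 0.05 in each comparison, long RNA at the left and short RNA at the right; full colours are the libraries as deposited and pale colours the libraries at matched depth. In long RNA of nodules against exponential culture, lower calls go from 6726 to 3214 and higher calls from 885 to 776.

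In short RNA, which was treated to make 5′ triphosphate ends ligatable and was not fragmented, several of the regions named in long RNA moved in the same direction. In stationary culture, the window of replicon b from 28001 to 28500 on the reverse strand rose by 7.25 ± 0.31 (log2 change ± SE, adjusted p = 5.5e-07), from 0.248 ± 0.0725 to 116 ± 31.0, at least 88.3 times with unlisted bases at the floor. The chromosomal windows from 1465001 and from 1480001 on the forward strand fell from 66.8 ± 18.1 to 0.198 ± 0.177 and from 61.2 ± 14.1 to 0.179 ± 0.181. In nodules, the reverse strand of replicon a from 447001 to 447500 was at 486 ± 195 against 1.18 ± 0.302 in exponential and 0.999 ± 0.138 in stationary culture. The forward strand of replicon a from 413001 to 413500 rose from 0.0800 ± 0.0858 in exponential culture to 131 ± 66.1 in nodules. In the forward run of the chromosome from 1377501 to 1397000 the first window differed from the rest: short RNA was at 49.4 ± 15.1 in nodules over the whole run but at 4.36 ± 0.984 without that window, against 35.0 ± 6.64 and 30.6 ± 6.03 in exponential culture.

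The chromosomal windows from 702001 (forward strand, 107 ± 29.3 in exponential culture) and from 2934501 (reverse strand, 86.2 ± 19.9) were listed at 0 in the short-RNA libraries of nodules, and so was the window of replicon b from 1548501 on the forward strand, at 82.4 ± 9.26 in stationary culture. Of 12340 windows tested, 3383 were higher and 4614 lower in stationary than in exponential culture, 2142 higher and 7368 lower in nodules than in exponential culture, and 2284 higher and 6348 lower in nodules than in stationary culture. Lower calls made up 77.5% and 73.5% of the calls in the nodule comparisons as deposited, 67.7% and 65.0% at matched depth, and 55.9% in both with upper quartile size factors. With quantile normalisation they made up 62.5% and 61.3%. The balance of stationary against exponential culture had 57.7% lower calls, 48.6% with upper quartile size factors and 83.5% when a window was summarised by its median depth. The median log2 change of all windows in this comparison was -0.23, and 0.11 with upper quartile size factors. The median was -1.51 for nodules against exponential and -1.07 against stationary culture, and -0.37 and -0.32 with upper quartile size factors. In the simulation, unchanged windows of short RNA had medians of -1.19 and -1.13 in these comparisons as deposited, and -0.30 in both at matched depth. The simulation took the levels of all states from exponential culture, and its medians are over the 9200 simulated windows that passed the filter. Its median against stationary culture as deposited thus cannot tell whether the observed one exceeds an effect of the floor. At matched depth with recomputed size factors the median was -0.69 and -0.04, a setting that changes both depth and scaling. Matched depth alone moved the median against stationary culture from -0.84 to -0.08 on the chromosome. On replicon a it went from -1.45 to -1.18 and on replicon b from -1.60 to -1.50. A general fall in short RNA against stationary culture thus depends on both depth and scaling.

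The share of each library's depth on the 3 replicons differed between states. In long RNA, replicon a held 3.91% ± 0.228 of the depth in exponential culture, 8.71% ± 0.207 in stationary culture and 21.4% ± 1.67 in nodules (SD, n = 3 each). Replicon b held 7.77% ± 0.0792, 17.8% ± 0.678 and 7.97% ± 0.553, and the chromosome 88.3% ± 0.247, 73.5% ± 0.703 and 70.7% ± 1.35. In short RNA the shares of replicon a were 7.22% ± 0.949, 14.6% ± 0.696 and 13.4% ± 1.13. Those of replicon b were 11.2% ± 0.629, 18.98% ± 0.814 and 9.45% ± 0.788, and those of the chromosome 81.5% ± 1.57, 66.5% ± 1.47 and 77.2% ± 1.66. In exact two-sided permutation tests of 3 libraries against 3, the smallest possible p is 0.1, so none of the 18 can be under 0.05. All reached 0.1 except replicon b in long RNA of nodules against exponential culture (p = 0.7, exact permutation test) and replicon a in short RNA of nodules against stationary culture (p = 0.2).

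The 4 runs of replicon a named above were chosen as higher in nodules, so a smaller difference without them follows from the choice. Without them, its share of the long-RNA depth was 6.99% ± 0.374 in nodules, 3.89% ± 0.227 in exponential and 8.70% ± 0.207 in stationary culture. At matched depth the long-RNA shares of replicon a were 2.44% ± 0.260, 8.18% ± 0.279 and 24.5% ± 1.52, and replicon b held 8.20% ± 0.606 in nodules against 5.10% ± 0.284 in exponential culture. In short RNA at matched depth replicon a held 5.82% ± 0.989, 14.7% ± 0.341 and 19.6% ± 1.31, so that nodules lay above stationary culture there. Replicon b held 11.5% ± 0.904 in nodules against 9.03% ± 0.569 in exponential culture, the other way round than as deposited.

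**Figure D4:**
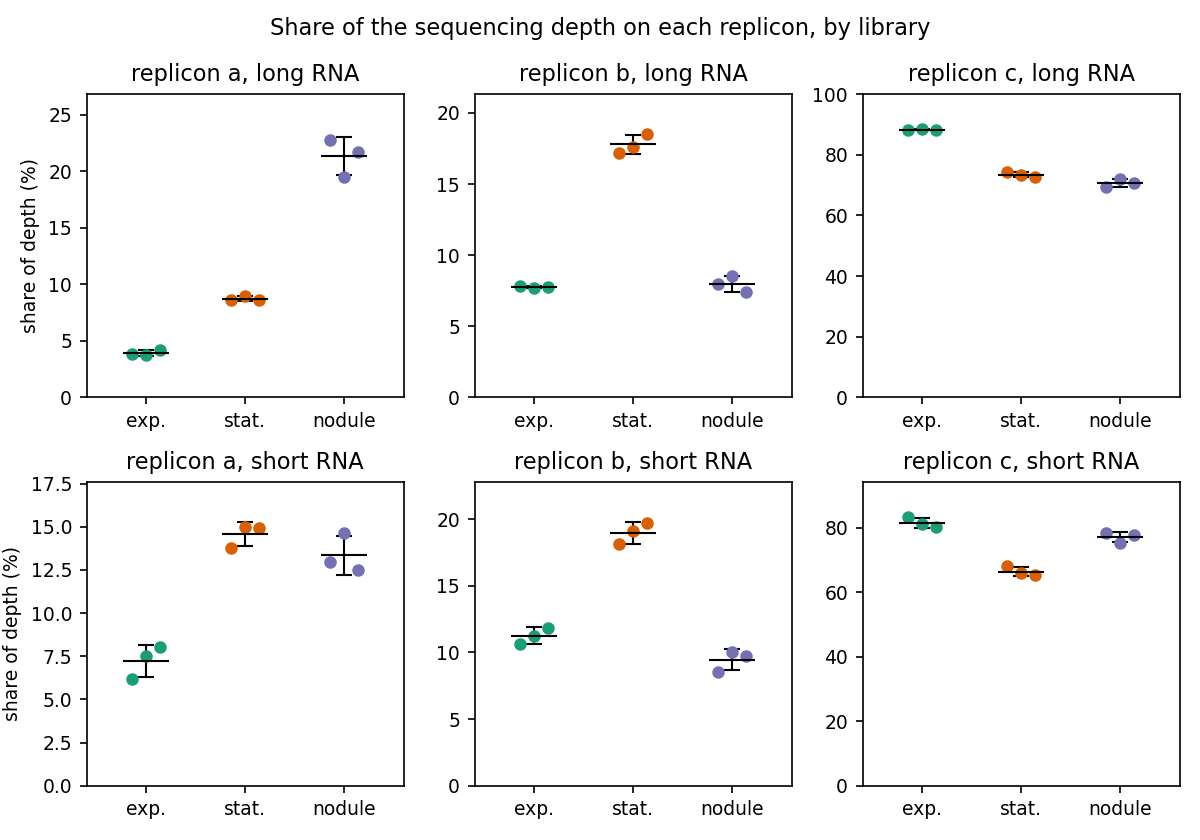
Share of the summed depth (percent) on replicons a, b and c in each library, long RNA above and short RNA below; points are libraries, horizontal bars the means of 3 and error bars their SDs. In long RNA the nodule libraries lie at 21.4% on replicon a on average, above 8.71% in stationary and 3.91% in exponential culture.

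Depth on the strand with less depth in a pair of facing windows was taken as opposite-strand depth, since no annotation gave the sense strand. That strand was set by the mean over the 9 libraries of a fraction, and set anew from the matched values at matched depth. A pair whose deeper strand switches in a single state thus adds to the share of that state. Its share in long RNA was 2.83% ± 0.143 in exponential culture, 3.59% ± 0.255 in stationary culture and 2.82% ± 0.748 in nodules (SD, n = 3 each). In short RNA it was 9.42% ± 0.909, 11.7% ± 1.27 and 7.51% ± 2.06. The rise in stationary culture in long RNA (p = 0.1, exact permutation test) and the fall from stationary culture to nodules in short RNA (p = 0.1) had no overlap between libraries, which chance gives in 10% of such comparisons, and the other 4 comparisons overlapped as deposited. By median depth the long-RNA share of stationary culture lay below that of exponential culture instead (0.992% ± 0.0853 against 1.20% ± 0.109, p = 0.1, exact permutation test). At matched depth nodules lay above exponential culture without overlap, at 1.83% ± 0.192 against 1.33% ± 0.106 in long RNA and 9.42% ± 0.825 against 6.03% ± 0.471 in short RNA. At matched depth the fall in short RNA was not seen, with 8.91% ± 0.293 in stationary culture and 9.42% ± 0.825 in nodules.

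Short RNA rose sharply at single bases. Sites where all 3 libraries of a state had a depth of at least 30 and at least 5 times that of the base before numbered 1272 in exponential culture, 2273 in stationary culture and 243 in nodules; this rule was chosen after the data were seen, and since its threshold is on raw depth the counts are not comparable between states. Long RNA rose at the same sites. Its depth over the 100 nt downstream exceeded that upstream by a median log2 of 3.15 in exponential culture, 3.07 in stationary culture and 3.25 in nodules, and by at least 2 times at 79.3%, 77.4% and 66.7% of the sites. On the opposite strand the same step was found at 5.58%, 5.90% and 2.47% of the sites. The lower and upper quartiles of the log2 step were 1.46 and 4.77 in exponential and 1.20 and 4.94 in stationary culture. In nodules they were 0 and 5.32. The floor lies higher in the nodule libraries, so more weakly covered bases are listed at 0 there on both strands. The steps and opposite-strand percentages of nodules are thus not comparable with those of cultures. Of the regions above, the run of replicon a from 442001 to 451500 had such a rise on its reverse strand at 451112, at a short-RNA depth of 1254 ± 551 in nodules, and the run from 453001 one on the forward strand at 453147 (226 ± 115). The run on the reverse strand of the chromosome from 1619501 to 1623500 had one at 1623263 (2196 ± 138 in nodules), that from 779001 to 781500 one at 781340 (231 ± 77.4 in stationary culture), and the forward run from 3164001 one at 3164321 (478 ± 143 in stationary culture). In exponential culture, the forward run of the chromosome from 1460501 had one just upstream, at 1460363 (342 ± 105).

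**Figure D5:**
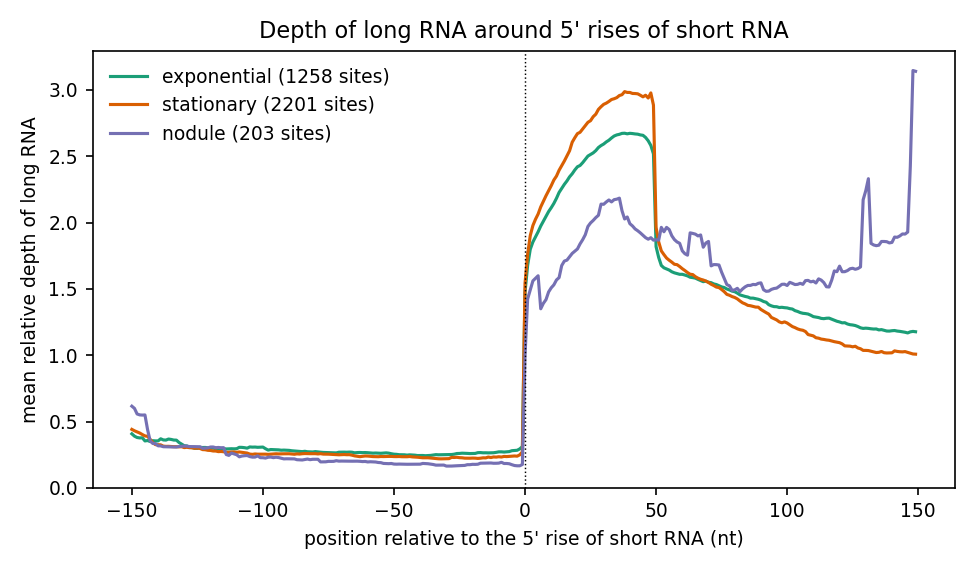
Mean depth of long RNA at each base from 150 nt upstream to 149 nt downstream of the 5′ rises of short RNA on the same strand, relative to the mean over that span at each site; lines are the states, over 1258 exponential, 2201 stationary and 203 nodule sites with any long-RNA depth. The relative depth steps from 0.311 to 1.47 in exponential culture and from 0.272 to 1.54 in stationary culture between the base before the rise and the rise.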

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

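All tests of explanations in this part were chosen after the results were seen.

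The share of depth on the chromosome moved in opposite directions between nodules and stationary culture: it differed by -2.82 percentage points in long RNA, where each nodule library lay below each stationary one, and by 10.7 points in short RNA, where each lay above. The difference between the fractions itself was not tested. Leaving out the 10 windows with the most depth left a difference of 9.01 points in short RNA, which argues against those 10 as the whole cause. The 100 deepest windows of the chromosome held 54.8% of its short-RNA depth in nodules and 17.7% in stationary culture. Leaving out more windows was not tested, so a larger set of deep windows stays open. At matched depth the difference in short RNA was 2.52 points, with 66.7% to 70.3% in nodules against 66.0% to 67.0% in stationary culture, so the floor and the ceiling of the files may account for most of the short-RNA difference, but in long RNA it grew to -7.40 points. By median depth both differences were negative (-8.46 in long and -2.74 in short RNA), so the contrast depends on how depth was summarised, and no biological explanation was tested.

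Lower calls dominated in long RNA of nodules against exponential culture. At matched depth they were still 80.6% of the calls, which argues against a floor that differs between the libraries as the whole cause. With total depth size factors at matched depth they were 71.7%. Total depth is itself drawn by a few deep regions. The 4 longest nodule runs of replicon a held 15.4% of all long-RNA depth in nodules and 0.0248% in exponential culture. Upper quartile size factors could not be run in long RNA, so the scaling stays open as a cause. Longer inserts in the nodule libraries of long RNA stay open: short RNA, with 1 insert range for all states, had 67.7% lower calls at matched depth, which does not exclude an effect of inserts in long RNA, and the 2 cannot be told apart since every long-RNA nodule library has the longer inserts. A lower output of most chromosomal regions in nodule bacteria is an open, untested explanation.

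The higher share of replicon a in long RNA of nodules than of exponential culture (17.4 points as deposited) was weighed against 3 explanations. DNA carried over with the RNA would cover both strands of all of replicon a alike, but its 100 deepest windows held 81.9% of its nodule depth, which argues against DNA. At matched depth, with the same normalised floor and ceiling in every library, the difference was 22.0 points. This argues against limits that differ between the libraries as its whole cause. Nodule depth under the floor is not listed and cannot be restored by resampling. The test thus compares shares of listed depth only, and cannot exclude an effect of the floor or the ceiling themselves. Without the 4 longest runs higher in nodules the difference was 3.10 points, but the runs were chosen as higher in nodules, so this test leaves open whether a few regions or many carry the difference. That these runs hold genes used in nitrogen fixation is a hypothesis that needs an annotation of this assembly, and was not tested.

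Other splits of the libraries were counted for each comparison in a fit of the 6 libraries compared. With 10 splits of 6 libraries into 3 and 3, a share under 0.05 cannot be reached; in each comparison 1 of the 10 splits, the real one, gave as many calls. In long RNA the real splits called 7775 windows for stationary against exponential culture, 7251 for nodules against exponential and 6787 for nodules against stationary culture, and in short RNA 9704, 8860 and 7905. The highest of the other splits was 0 by limma in each comparison, and at most 23, 15, 42, 61, 32 and 145 windows had an unadjusted p under 0.05 in any of them. Each other split puts libraries of both states into each group, so the difference between states widens its spread. Few calls in these splits follow from that, and the counts do not show what chance alone would give.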

How the results depend on the processing

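Matched depth, its forms and leaving out windows at the ceiling were added after the data were seen; the other settings were fixed before the data were examined. Counts of calls are given in the order stationary against exponential, nodules against exponential and nodules against stationary culture, and the cause of a change was not tested unless the setting itself gives it. Fewer or more windows tested moved the counts most: without a depth filter there were 11231, 11979 and 10919 calls in long RNA and 11961, 14029 and 12562 in short RNA, and with a filter of 10 there were 1496, 1759 and 1707 in long and 1750, 1988 and 1941 in short RNA. The median depth of a window gave 4345 calls for nodules against stationary culture in long RNA, and 4372, 5297 and 2126 calls in short RNA. For the nodule comparisons, matched depth gave 3990 and 3634 calls in long and 5171 and 4570 in short RNA. With total depth size factors at matched depth there were 3648 and 3388, and 5086 and 4632; with recomputed size factors 3855 and 3426, and 5156 and 4450; and without resampling 3171 and 2990, and 5022 and 4846. The lower share of calls ranged from 71.7% to 92.6% and from 70.1% to 91.9% over all settings in the long-RNA nodule comparisons, and from 55.9% to 92.4% and from 55.7% to 81.8% in short RNA. Upper quartile size factors could not be run in long RNA, where the quartile is 0 in nodules, and the alternatives for gene lists were not run because the lists are void.

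Leaving out 1 library at a time gave 5835 to 6113, 6972 to 7984 and 6658 to 7573 calls in long RNA, and 6849 to 7060, 8574 to 9971 and 7619 to 9195 in short RNA. No pairing by replicate number was detected: the deviations of libraries with the same number correlated between -0.0138 and 0.166 in long and between -0.109 and 0.0398 in short RNA. Those of libraries with different numbers correlated between -0.177 and 0.154 and between -0.114 and 0.107. With 3 libraries per state this does not exclude a pairing. A replicate block gave 6489, 7568 and 7160 calls in long and 7796, 9421 and 8541 in short RNA. Of 1310 combinations of a named window and a setting, 1300 kept the direction and the call. The other 10 kept the direction and lost the call with voom weights in short RNA (limma, adjusted p up to 0.641). The named windows were picked as the largest changes among those called, so this largely follows from the choice. It does not speak for the other windows called.

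Of 216 alternative values of 24 share differences, 18 changed sign. For replicon b in long RNA of nodules against exponential culture the difference of 0.198 points ranged from -0.0847 to 0.468 without 1 library. The opposite-strand share of long RNA in nodules minus exponential culture (-0.00791 points) ranged from -0.403 to 0.341 without 1 library and was 0.330 without the 10 windows with the most depth, 0.212 by median depth and 0.502 at matched depth. By median depth, the opposite-strand difference became -0.212 for stationary minus exponential culture and 0.424 for nodules minus stationary culture in long RNA, and -0.623 and 0.341 in short RNA; the share of replicon a in short RNA of nodules minus stationary culture became 13.5 and that of the chromosome -2.74. At matched depth in short RNA, replicon a became 4.83 in nodules minus stationary culture, replicon b 2.51 in nodules minus exponential culture, and the opposite-strand share 3.40 and 0.509 in nodules minus exponential and minus stationary culture. Depth limits the nodule comparisons: in nodules a window needs a normalised depth of about 8.01 to 18.0 at a base to be listed in long RNA.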

Other observations

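All values in this part were chosen after the data were seen. In nodules, several regions outside the 4 longest runs of replicon a stood out in long RNA. The reverse strand of replicon a from 64501 to 69000 was at 48.1 ± 10.5 in long RNA of nodules against 1.89 ± 0.0694 in exponential culture (SD, n = 3 each), and began at a 5′ rise of short RNA at 68762 with a depth of 2201 ± 653. On replicon b, the forward strand from 1606001 to 1608500 was at 16.1 ± 0.510 against 0.0617 ± 0.0421 in exponential culture, and on the chromosome the forward strand from 3108501 to 3110500 at 14.02 ± 2.37 against 0.0938 ± 0.0812.

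Long and short RNA gave the same direction in most windows called in both. At matched depth, 4199 of 4313 windows called in both fractions for stationary against exponential culture had the same direction, 2687 of 2755 for nodules against exponential and 1812 of 1954 for nodules against stationary culture. Independent lists of the same sizes would share 115 windows higher in nodules than in exponential culture, and 509 were shared; of lower windows 1442 would be shared and 2178 were. The fractions come from the same kinds of samples, and the labels do not say whether from the same extracts.

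The 5′ rises of short RNA overlapped between states. Of the 1272 sites of exponential culture, 657 (51.7%) lay within 5 nt of a site of stationary culture. Of the 243 nodule sites, 95 (39.1%) lay within 5 nt of an exponential site and 164 (67.5%) within 5 nt of a stationary one, with 1272 and 2273 sites to match. At 22.2% of the nodule sites long RNA of nodules had no listed depth over the 100 nt downstream, against 1.57% and 4.22% in exponential and stationary culture. The long-RNA libraries of nodules were far shallower and their floor lay higher, so this difference cannot be told apart from one of depth.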
